A study of Arabidopsis thaliana with 6 samples.

How the data were processed

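RNA was measured in 6 samples of whole wild-type Arabidopsis thaliana seedlings, 3 exposed to control white noise (10 dB on average) and 3 to traffic noise (75 dB on average) for 48 h. Per the labels' protocols, plates were wrapped in foil to keep out light, RNA was extracted with Trizol, and libraries were made with the Lexogen QuantSeq kit, which reads the 3′ ends of polyadenylated transcripts. Such counts reflect transcript ends and do not scale with transcript length. Bowtie2, bedtools and the TAIR10 build are named in the submitters' processing notes, with no versions, roles or order. How reads with several matches were treated and whether counting used strand are not given in the sources used here, so near-identical copies and overlapping loci can share or duplicate counts.

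The authors deposited, per sample, a table of raw counts per gene symbol, with whole numbers and no normalization. Each table had the same 33139 rows, of which 218 carried no gene name. These held 0.0431% to 0.0886% of the counts and were left out of totals and tests. Of the 32921 named rows, 32506 could be tied to 1 locus through the symbols of the TAIR10.1 annotation. A further 412 rows shared 195 repeated symbols and are reported by symbol, and the other 3 were tied to no locus. Because that annotation is not certain to be the one used for counting, it served for names, product descriptions, overlaps between loci and transcript lengths, and no coordinates are given. Totals over named rows ran from 17540009 to 20780363 counts. A floor of 3 counts is 0.144 to 0.171 CPM in a library.

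Groups, tests, gene lists, families and most alternatives were chosen before the data were examined. Loci were kept by edgeR's filterByExpr, which left 19112, and libraries were scaled with TMM factors. The main test was edgeR's quasi-likelihood F test with robust fitting, adjusted over all loci by Benjamini-Hochberg at a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute fold change over the square root of F. CPM values are scaled by TMM and given as mean ± SD over 3 libraries. DESeq2 (Wald test, its own size factors and filter) and limma-voom were run as alternatives. DESeq2's independent filter lay at a mean of 583 counts, it gave no p-value for 223 loci, and loci without an adjusted p were not counted as called or lost.

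Gene sets were compared with the other loci by limma's camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera with an estimated correlation and limma's fry test were run beside it. There were 20 lists of 293 genes, of which 284 had a row of their own and 221 were tested. In all, 19 lists had at least 3 tested members; the root hair list did not and was not tested. Families came from words in product descriptions: 45 were named and 40 had 10 to 500 tested members. Camera's direction was down for cell wall expansion, whose median and mean were above 0, and for hypoxia, whose mean was above 0. Seed storage had a median above 0 and a mean below it. Adjustment was over the 19 lists or the 40 families. Enrichment of families among DESeq2 calls used Fisher's exact test over protein-coding loci with an adjusted p, with 50 tests adjusted together. Shares of counts were compared by 2-sided exact permutation tests, whose smallest p with 3 against 3 is 0.1. Only the share of plastid and mitochondrial loci in total was planned, and the other classes were added later.

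Named loci were fixed by rule. Per direction these were the 10 with the largest fold change and the 5 with the smallest p among loci past the edgeR threshold, separated between groups and with at least 20 counts on average. Where none passed, the 5 with the smallest p were taken. From each list the rule took up to 4 members with the smallest p. As edgeR called almost nothing, the same rule was also applied to DESeq2 calls tied to 1 locus, a choice made after the calls were seen. The text names only part of the loci these rules reached. One item is not reported here.

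The scripts were tested on counts simulated from the means, dispersions and library sizes of this comparison over 19112 loci, with 200 loci changed in each of 3 runs. Of loci changed by a factor of 2, 4, 8 and 16, edgeR recovered 2.67%, 29.3%, 48.7% and 72.0%, and DESeq2 11.3%, 46.7%, 66.0% and 85.3%. At a mean of at least 500 counts edgeR recovered 8.33%, 85.4%, 97.5% and 100% of them. False calls made up 6.53% of edgeR's and 45.6% of DESeq2's. These shares hold for the changes simulated. All libraries were drawn with the same dispersion per locus, so the missing loci of control replicate 3 were not reproduced. Camera recovered the shifted set and called 0 of 39 unshifted sets, which were simulated without correlation between genes. Software was R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.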

Results

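Seedlings of wild-type Arabidopsis thaliana, the small crucifer used as a model plant, germinated in the dark on sealed agar plates inside a sound-proof facility. For 48 h they were exposed either to recorded urban traffic noise, averaging 75 dB, or to background white noise, averaging 10 dB, as the control. RNA from whole seedlings was made into libraries by a method that reads the 3′ ends of transcripts, and each group held 3 libraries. The control libraries held 20780363, 18399391 and 17540009 counts on named loci for replicates 1 to 3, and the traffic noise libraries 20016238, 20605708 and 19782106. Nothing in the labels says that replicates came from separate plates or batches of seed, so the p-values measure only the spread between these samples, which may be technical.

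The libraries of the control group differed among themselves more than those of the traffic noise group. Control replicate 3 had counts on 16128 loci, against 20026 to 20287 in the other 5 libraries, and its mean correlation with the others was 0.742, against 0.810 to 0.829 for the rest (Pearson's r, across loci, of log2 CPM, which is counts scaled to library size; loci are not independent replicates). It alone was set apart by the first principal component, with 52.7% of the variance. Control replicate 1 drew 16.1% of its counts from plastid and mitochondrial loci (95% Wilson interval 16.07 to 16.11), and the other libraries 10.1% to 11.7%. These intervals and all count floors cover counting error only.

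**Figure D1:**
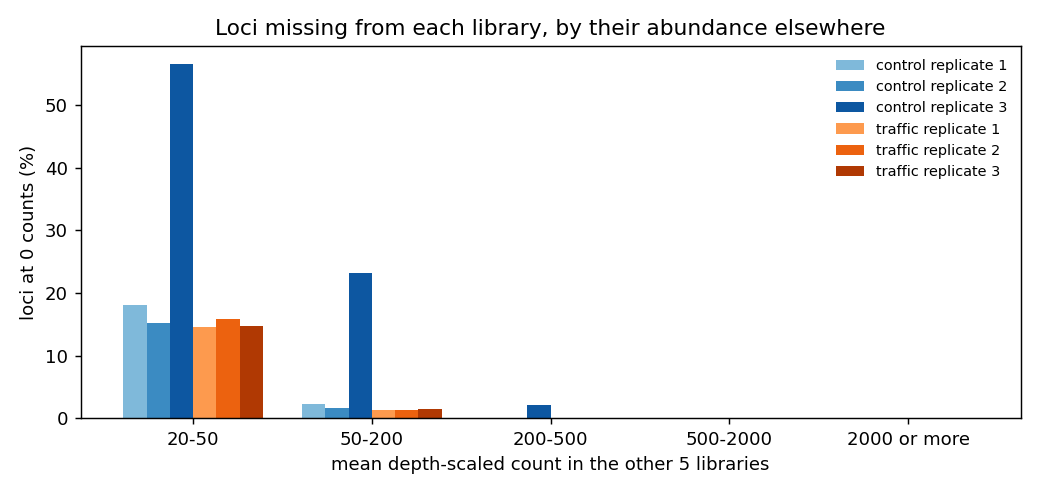
Loci at 0 counts in each library (vertical axis, percent), grouped by their mean depth-scaled count in the other 5 libraries (horizontal axis); each bar is 1 library. Among loci with 50 to 200 counts elsewhere, 23.1% were at 0 in control replicate 3 and 1.34% to 2.21% in each of the other libraries.

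The comparison of traffic noise with control asks which transcripts of dark-grown seedlings differ in level between the groups after 48 h. Sound type and sound level differed together between the groups, so their effects cannot be told apart. Organelle isoleucine tRNA, malate synthase and an abundant non-coding RNA were lower after traffic noise, and a small heat shock protein gene was higher, each by a margin several times its standard error. Only the tRNA passed the main test, however. The libraries were made to read polyadenylated ends, so counts on a tRNA may reflect its capture as well as its level. These were not told apart. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 19112 loci, 0 loci were higher and 2 lower at an adjusted p of 0.05. At an unadjusted p under 0.05, 665 were higher and 760 lower. Both that passed are copies of trnI, whose log2 fold changes were -2.60 ± 0.30 and -2.57 ± 0.29 (fitted value ± SE, edgeR adjusted p = 0.0354 for each). The levels were 192.3 ± 65.4 and 190.0 ± 64.4 CPM in control and 31.7 ± 2.17 and 32.0 ± 0.883 CPM in traffic noise (mean ± SD, n = 3). These rows share 1 symbol and their reads cannot be assigned to a copy with certainty; neither passed edgeR without control replicate 1 or without any 1 of the traffic noise libraries, where 0 loci were called.

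The spread between libraries was wide, with a common biological coefficient of variation of 0.757. Other tests on the same counts called more loci. DESeq2 called 84 higher and 130 lower at an adjusted p of 0.05, among the 4365 loci for which it gave one, and limma-voom called 4 and 8. In counts simulated for this comparison over 19112 loci, 45.6% of DESeq2's calls were false (263 of 577), against 6.53% of edgeR's (16 of 245). Among simulated loci with a mean of at least 500 counts the false shares were 17.7% and 3.31%. The DESeq2 calls below are therefore given with their values and are not read as established changes. All 214 had an unadjusted edgeR p under 0.05, and in 211 the libraries of one group all lay above those of the other. Both largely follow from choosing loci by a test on the same counts, so they lend the calls no separate support. Such separation held for 16.4% of all tested loci, where chance gives 10%. Which loci were called also depended on single libraries. Without control replicate 2 DESeq2 called 721 higher and 354 lower, of which 77 and 127 were among the calls from all 6 libraries. Without control replicate 1 it called 82 and 33, with 13 and 20 of them shared, and without control replicate 3 it called 113 and 73, with 33 and 47 shared. Without traffic replicate 1 it called 58 and 119, with 43 and 83 shared. In that fit only 62 of the 84 higher and 114 of the 130 lower calls had an adjusted p. Without traffic replicate 2 it called 13 and 69, and without traffic replicate 3 it called 15 and 86, with 7 and 15 shared in each case.

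MLS and ICL encode enzymes of the glyoxylate cycle, which turns stored fat into sugar precursors in germinating seedlings; both had lower mean counts after traffic noise, and neither passed the main test. MLS (AT5G03860), the malate synthase, stood at 485 ± 152 CPM in control and 101 ± 31.0 CPM in traffic noise (SD, n = 3). Its log2 fold change was -2.27 ± 0.31, with an adjusted p of 0.0839 in edgeR, 6.6e-10 in DESeq2 and 0.00223 in limma-voom. Among loci with a mean of at least 500 counts, a filter chosen after the data were seen, MLS fell (edgeR adjusted p = 0.0294). ICL (AT3G21720), the isocitrate lyase of the same cycle, had a log2 fold change of -1.11 ± 0.38 and adjusted p-values of 0.527 in edgeR and 0.0502 in DESeq2. Its level was 4053 ± 1740 CPM in control and 1883 ± 866 CPM in traffic noise. The fatty acid oxidation gene MFP2 had a log2 fold change of -0.48 ± 0.24, while that of the triacylglycerol lipase SDP1 was 0.92 ± 0.40; neither passed. Of the 12 genes of lipid reserve mobilisation, 10 had negative fold changes, with a median of -0.28 (camera adjusted p = 0.127). By edgeR 0 of them passed over all genes tested, and 1, MLS, did when adjusted over the list alone. Without control replicate 3 the list passed, with a median of -0.33 (camera adjusted p = 0.0372; adjusted p = 0.624 with an estimated correlation). Of 18 matched seed storage and maturation genes, 5 had enough counts to test and 0 passed; the most abundant of these, OLEO3, had a log2 fold change of 0.12 ± 0.46.

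**Figure D2:**
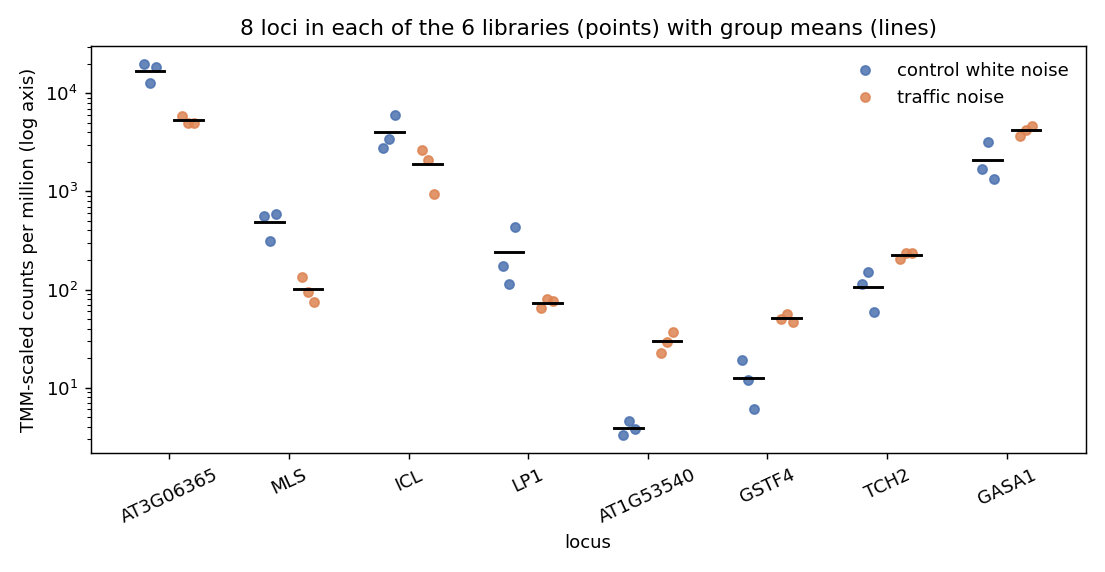
TMM-scaled CPM (vertical log axis) of 8 loci in each of the 6 libraries; points are libraries and black lines are group means. MLS lay near 485 CPM in control and 101 CPM in traffic noise, and AT1G53540 near 3.88 and 29.6 CPM, with no overlap between groups; of the 8 loci only AT3G06365, MLS and AT1G53540 came within an edgeR adjusted p of 0.0839.

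Transcripts of ribosomal proteins passed as a lower family at camera's preset correlation only. Of 310 tested genes whose product is described as a ribosomal protein, 245 had negative log2 fold changes, with a median of -0.46 against 0.05 for all tested loci (camera adjusted p = 6.36e-14 over 40 families). With an estimated correlation between genes the call was lost (camera adjusted p = 0.662, estimated correlation 0.156), and the fry test for a shared direction gave an adjusted p of 0.420. At the preset correlation the family also passed in 3 other splits of the libraries into equal groups (smallest camera adjusted p = 7.3e-09). No single member passed edgeR. DESeq2 called 38 of the 193 with enough counts lower and 0 higher, where 4.88 lower would be expected (Fisher's exact test, adjusted p = 1.1e-23). That test takes genes as independent, so its p does not measure the spread between samples and does not restore the lost call. Among them were RPL18, at 651 ± 142 CPM in control and 358 ± 51.5 CPM in traffic noise, RPS5A, at 763 ± 84.5 and 439 ± 121 CPM, and PRPS20, a plastid ribosome protein, at 247 ± 37.2 and 114 ± 10.8 CPM (SD, n = 3). Together, nuclear ribosomal protein genes took 4.45% ± 0.476 of counts in control and 3.14% ± 0.467 in traffic noise (exact permutation test, 2-sided, p = 0.1, the smallest that 3 against 3 can give). That share was not among the planned tests. Many of these genes have close paralogs, so counts of single members are uncertain.

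Other families passed camera at its preset correlation and not at an estimated one. Fold changes were negative for 30 of 42 histone genes (median -0.29, camera adjusted p = 0.00261), 28 of 40 proteasome genes (median -0.23, camera adjusted p = 0.00789), 21 of 31 extensins (median -0.30, camera adjusted p = 0.0285) and 32 of 52 lipid transfer proteins (median -0.14, camera adjusted p = 0.0475). Auxin-responsive and SAUR genes, a class of small growth-related transcripts induced by the hormone auxin, had positive fold changes in 75 of 99 (median 0.50, camera adjusted p = 0.00524). With an estimated correlation 0 of the 6 families passed: camera's adjusted p was 0.662 for the lower families and 0.858 for the auxin family. Nor did any pass the fry test, with an adjusted p of 0.470 for extensins and 0.420 for each of the others. Without traffic replicate 3 only the ribosomal proteins passed, and without control replicate 1 only ribosomal proteins, histones and proteasome genes. Extensins were also lost without control replicate 2 (camera adjusted p = 0.261), and their median was -0.60 without traffic replicate 2. Of the 6 fits with a library left out, lipid transfer proteins passed only in that without traffic replicate 2 (median -0.25). LP1 (AT2G38540), a lipid transfer protein, had 240 ± 170 CPM in control and 73.5 ± 7.88 CPM in traffic noise (log2 fold change -1.71 ± 0.42, adjusted p = 0.465 in edgeR and 0.00463 in DESeq2). Its log2 fold change lay between -2.04 and -0.96 in 18 settings. Control replicate 3 lay lowest of the 6 libraries for the auxin family.

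**Figure D3:**
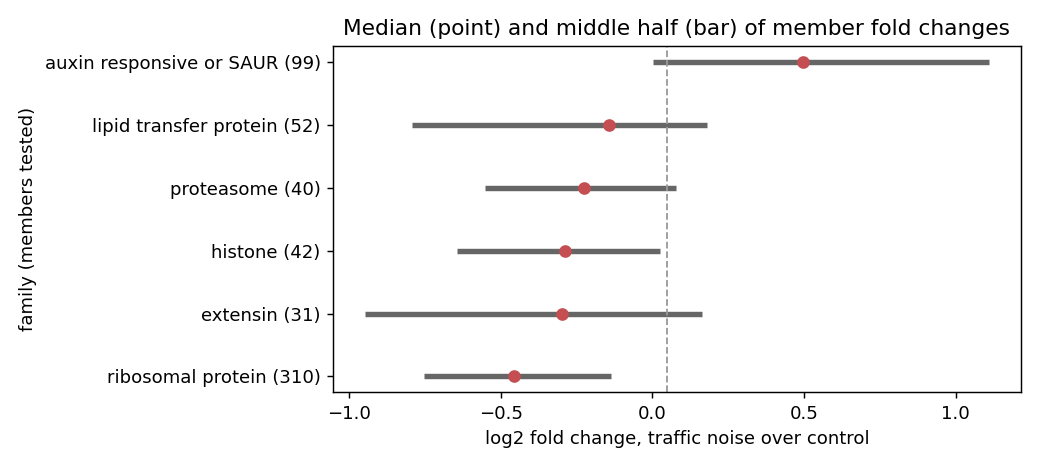
Log2 fold change, traffic noise over control (horizontal axis), for the members of the 6 families past a camera adjusted p of 0.05 at the preset correlation; points are medians, bars span the quartiles, numbers in brackets are members tested, and the dashed line is the median of all tested loci (0.05). The ribosomal protein bar lies wholly below that line.

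Among the gene lists, the gibberellin list was the 1 of 19 tested that passed. All 12 tested members had positive log2 fold changes, with a median of 0.58 (camera adjusted p = 0.00651; adjusted p = 0.433 with an estimated correlation). The fry test gave it an adjusted p of 0.0342, and no other list passed that test. The list mixes genes with opposite roles in this growth hormone's pathway. GASA1 (AT1G75750), a gibberellin-regulated gene, had 2076 ± 986 CPM in control and 4189 ± 464 CPM in traffic noise, with a log2 fold change of 1.01 ± 0.30 (adjusted p = 0.493 in edgeR and 0.0281 in DESeq2). GA2OX6, an enzyme that inactivates gibberellin, was at 3.24 ± 1.64 and 7.90 ± 1.17 CPM, and the receptor GID1A at 16.3 ± 4.12 and 25.3 ± 4.28 CPM. The synthesis gene GA20OX2 was at 0.05, 0 and 0 CPM in the control libraries and at 2.61, 1.77 and 2.35 CPM in traffic noise. By edgeR 0 members passed, over all genes or adjusted over the list alone. Control replicates 1 and 3 had the lowest list levels, and without control replicate 1 the list did not pass (median 0.39, camera adjusted p = 0.116).

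Auxin and heat shock lists lay just outside the threshold at camera's preset correlation. With an estimated correlation they lay far from it (camera adjusted p = 0.727 for auxin and 0.667 for heat shock). Of 16 auxin genes, 14 had positive fold changes, with a median of 0.56 (camera adjusted p = 0.0678). The median was 0.25 without control replicate 3 (camera adjusted p = 0.208), and without control replicate 2 the list passed with a median of 0.84 (camera adjusted p = 0.0198; adjusted p = 0.718 with an estimated correlation). SHY2, an auxin-response repressor, had a log2 fold change of 0.92 ± 0.29 and IAA2 one of 0.63 ± 0.22. Neither passed, and SHY2 overlaps a neighbouring locus with near-equal counts. Of 10 heat shock and chaperone genes, 7 were positive, with a median of 1.11 (camera adjusted p = 0.0678). That median lay between 0.63 and 2.13 in 20 settings. The wider family described as heat shock or chaperone proteins had 102 positive and 93 negative of 195, with a median of 0.07 (camera adjusted p = 0.842). HSP17.6II was at 1.58 ± 2.12 CPM in control and 16.7 ± 3.57 CPM in traffic noise, and HSP17.4, which overlaps another locus with near-equal counts, at 1.62 ± 1.47 and 15.2 ± 4.23 CPM. Both had 0 CPM in control replicate 3, the library short of low-count loci. Without that library the list passed, with a median of 0.63 (camera adjusted p = 0.021; adjusted p = 0.520 with an estimated correlation). AT1G53540, an HSP20-like chaperone outside the list, had the smallest p among loci with higher counts: 3.88 ± 0.660 CPM in control and 29.6 ± 7.21 CPM in traffic noise, a 7.61-fold difference (log2 fold change 2.93 ± 0.41, edgeR adjusted p = 0.0839).

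Touch, wounding and defence lists did not pass the threshold as sets. Touch and early wounding genes split 9 to 7 in sign (median 0.17, camera adjusted p = 0.72). Their median lay between 0.07 and 0.82 in 22 settings, without passing. In that list the calmodulin-like gene TCH2 (AT5G37770), known for its induction by touch, was at 107 ± 45.6 CPM in control and 225 ± 17.3 CPM in traffic noise (log2 fold change 1.07 ± 0.31, adjusted p = 0.493 in edgeR and 0.0314 in DESeq2). TCH3 had a log2 fold change of 1.21 ± 0.45, and RRTF1, a redox-responsive transcription factor gene of the same list, one of -1.95 ± 0.60, from 18.6 ± 15.1 CPM in control to 4.78 ± 1.05 CPM in traffic noise. Neither passed. RRTF1 overlaps a locus with near-equal counts, and its log2 fold change lay between -2.26 and -1.04 in 15 settings. Of 10 jasmonate genes, 7 were positive (median 0.42, camera adjusted p = 0.178), among them LOX4 with a log2 fold change of 1.93 ± 0.81, not past the threshold. Of 6 salicylate and defence genes, 4 were positive (median 0.20, camera adjusted p = 0.788). WRKY70, a defence transcription factor, was the 1 member to pass adjusted over the list alone, at 13.6 ± 1.84 and 32.1 ± 8.09 CPM. The reactive oxygen and glutathione list had a median of -0.19 (camera adjusted p = 0.862) and the hypoxia list one of -0.21 (0.788).

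No light or developmental list passed the threshold with all 6 libraries. Nuclear photosynthesis genes had a median of -0.09 over 26 members (camera adjusted p = 0.72), but without control replicate 3, which had the highest level of this list, the median was 0.49 and the list passed as higher (camera adjusted p = 0.021; adjusted p = 0.624 with an estimated correlation). Without control replicate 1 the median was -0.39 (camera adjusted p = 0.0817). CAB1, a chlorophyll-binding protein gene, had a log2 fold change of 0.93 ± 0.29 (adjusted p = 0.493 in edgeR and 0.0482 in DESeq2). The Rubisco small chain genes RBCS3B and RBCS2B had log2 fold changes of -0.44 ± 0.19 and -0.71 ± 0.30, and ELIP1 of the light signalling list one of -3.06 ± 0.95. None of these passed, and that of ELIP1 lay between -3.50 and -1.31 in 15 settings. Medians were -0.28 for light signalling and greening (camera adjusted p = 0.228), -0.44 for the cell cycle (0.194), 0.51 for the circadian clock (0.194), 0.48 for ethylene (0.178), -0.56 for flavonoid genes (0.72), 0.10 for cell wall expansion (0.788), 0.11 for the abscisic acid response (0.963), 0.12 for seed storage (0.963) and -0.01 for root markers (0.72). In the abscisic acid list the cold- and drought-induced gene KIN2 had a log2 fold change of -1.23 ± 0.31, and it passed adjusted over the list alone. Over all genes, edgeR called 0 members of any list.

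The remaining named loci include several that respond to stress or carry sugar. GSTF4, a glutathione S-transferase, was at 12.4 ± 6.64 CPM in control and 51.2 ± 4.54 CPM in traffic noise (log2 fold change 2.04 ± 0.41, adjusted p = 0.395 in edgeR and 0.00107 in DESeq2). Log2 fold changes were 1.54 ± 0.48 for the sucrose transporter SWEET11, 1.51 ± 0.50 for the trypsin inhibitor KTI1, 1.45 ± 0.37 for the glutaredoxin GRXS13 and 1.62 ± 0.36 for the kelch-repeat gene AT1G80440. They were 1.46 ± 0.29 for the knottin-like AT2G43535, 1.12 ± 0.22 for the uncharacterised AT4G13530 and 1.91 ± 0.44 for AT1G19530. AT4G35750, a SEC14-type lipid transfer gene, was at 317 ± 10.5 CPM in control and 727 ± 139 CPM in traffic noise. All of these were called by DESeq2 and none by edgeR. The log2 fold change of KTI1 lay between 1.16 and 2.56 in 18 settings. Lower by DESeq2 alone were AT4G11210, a dirigent-like gene (-1.53 ± 0.34), and AT5G63300, AT3G15200 and AT3G52390 (-1.59 ± 0.35, -1.52 ± 0.28 and -1.50 ± 0.46), each of which overlaps a locus with more counts. Of the 206 DESeq2 calls tied to 1 locus, at most 69 overlap another locus. At most 22 of these share near-equal counts with it, the smaller count being at least 0.8 of the larger. Both counts may be too high, since the mitochondrial rRNA locus rrn5 was matched to rows tied to no locus. The same holds for rrn26 in the count of overlaps.

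Several classes of structural and non-coding RNA took a smaller share of counts after traffic noise, though the rows annotated as ribosomal RNA did not in total. Nuclear 18S rRNA made up 1.41% ± 0.389 of counts in control and 0.621% ± 0.082 in traffic noise, and its copy AT2G01010 had a DESeq2 adjusted p of 0.000501. Mitochondrial 26S rRNA made up 1.68% ± 0.834 and 0.859% ± 0.0736 of counts, plastid 16S rRNA 0.221% ± 0.0622 and 0.115% ± 0.0384, organelle tRNA 0.785% ± 0.165 and 0.467% ± 0.0428, and small nuclear and nucleolar RNAs 0.281% ± 0.00663 and 0.203% ± 0.00626 (SD, n = 3). In each of these classes all 3 control libraries lay above all 3 traffic noise libraries (exact permutation test, 2-sided, p = 0.1, the smallest possible). The permutation p adjusted over all classes examined was 0.122 for each. These classes were not planned, so their separation is not independent support for the pattern. Plastid 23S rRNA, at 7.50% ± 2.11 and 7.68% ± 0.523, did not differ beyond its spread (exact permutation p = 0.9), nor did plastid and mitochondrial loci in total, at 12.4% ± 3.21 and 11.3% ± 0.389 (exact permutation p = 0.9). The total of rows annotated as ribosomal RNA overlapped between groups. It left out mitochondrial 26S rRNA and AT3G06365. This total took 11.5%, 8.00% and 7.96% of counts in the control libraries and 7.90%, 8.55% and 8.84% in traffic noise. AT3G06365, an uncharacterised non-coding RNA, took 1.67% ± 0.360 and 0.536% ± 0.0489 of counts (log2 fold change -1.67 ± 0.21, adjusted p = 0.0654 in edgeR and 1.58e-10 in DESeq2). AT1G08643 and AT2G03875, also non-coding, had log2 fold changes of -1.69 ± 0.26 and -1.53 ± 0.28.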

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

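Added after the data had been seen were the settings with a mean of at least 500 counts, with protein-coding nuclear loci only, DESeq2 with a library left out or with a block, the estimated correlation with a library left out, and the families under other settings than a block or an estimated correlation. With 0 loci higher and 2 lower by edgeR, counts were 84 and 130 by DESeq2, 4 and 8 by limma-voom, and 1 and 5 with no filter on low counts. No locus was lower with the replicate block, with organelle loci left out (which removes both called loci) or with protein-coding nuclear loci only. With a mean of at least 500 counts 4 were lower, and also without control replicate 3 it was 1 higher and 7 lower; fewer loci were tested there. Leaving out each library in turn gave 0 to 18 higher and 0 to 13 lower, the most without control replicate 2, and 0 to 4 lists and 1 to 7 families past the threshold. DESeq2 with a library left out gave 13 to 721 higher and 33 to 354 lower (73 without control replicate 3, 69 without traffic replicate 2 and 86 without traffic replicate 3), and with the replicate number as a block 172 and 155. Same-numbered samples did not deviate together (correlations -0.00899, 0.0137 and 0.0194), and not every sample correlated best with its own number. With 3 libraries per group this cannot exclude a shared plate or batch. With an estimated correlation 0 lists and 0 families passed, with all 6 libraries or with any 1 left out. Scaling by RLE or by totals, or asking for 10 counts in 3 libraries or a log2 fold change of at least 1, left the edgeR counts at 0 and 2.

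The log2 fold change of MLS stayed between -2.53 and -2.09 in 18 settings and passed in 7 of them, with adjusted p from 6.6e-10 (DESeq2) to 1.00 (edgeR without traffic replicate 2). That of AT1G53540 lay between 2.74 and 3.09 in 15 settings and passed in 3. The ribosomal protein median lay between -0.53 and -0.37 in 22 settings, and the gibberellin median between 0.26 and 0.85; the latter did not pass without control replicate 1, with a mean of at least 500 counts, with that and without control replicate 3, or with an estimated correlation. Fold changes of other sign, none of them past a threshold, were found for OLEO3 (-0.19 without control replicate 3, -0.14 without traffic replicate 1, -0.06 without traffic replicate 2, -0.21 with a mean of at least 500 counts and without control replicate 3), PAP85 (0.83 with the replicate block, 1.53 without control replicate 1, 0.11 without traffic replicate 1, and down to -1.04 without control replicate 3) and ABI3 (0.13 without control replicate 3, and down to -1.73 without traffic replicate 1). The photosynthesis list had a median of -0.39 without control replicate 1, 0.49 without control replicate 3 and 0.50 with a mean of at least 500 counts as well, and passed in the latter settings. Medians of other lists that turned sign, none past the threshold, ranged from -0.756 to 0.358 for hypoxia, -0.226 to 0.063 for reactive oxygen, -0.184 to 0.229 for cell wall expansion, -0.921 to 0.828 for seed storage and -0.080 to 0.107 for root markers. Except where a setting tests fewer loci or samples, the cause was not tested. Small changes could be missed. At totals of 17540009 to 20780363 counts, edgeR recovered 2.67% of simulated changes by a factor of 2, and 8.33% at a mean of at least 500 counts. The simulation used dispersions estimated from these libraries, the same for each library, and not the missing loci of control replicate 3. Depth was not varied.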

Other observations

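The comparison of plastid 23S with nuclear 18S rRNA was chosen only after those shares had been seen, as were the repeats of the low-energy test and the kelch-repeat, cell wall and histone genes named first. Beyond the lists, 4 kelch-repeat F-box genes, picked after their values were seen and not tested as a set, had higher mean counts after traffic noise. Such genes are known for marking cytokinin response regulators and phenylalanine ammonia-lyase for breakdown. AT1G80440 was at 64.4 ± 31.2 CPM in control and 198 ± 35.5 CPM in traffic noise, AT2G44130 at 103 ± 5.54 and 234 ± 79.9 CPM, and AT3G59940 at 249.5 ± 12.8 and 410.1 ± 25.2 CPM (SD, n = 3). Their DESeq2 adjusted p-values were 0.00189, 0.00463 and 0.0156, and none passed edgeR (adjusted p = 0.465, 0.465 and 0.486). AT2G44130 and AT3G59940 each overlap another locus with near-equal counts (1.06 and 0.952 times theirs), so their reads are uncertain. The remaining family member, AT1G15670, had a log2 fold change of 0.93 ± 0.32 (edgeR, SE) and did not pass DESeq2 (adjusted p = 0.0869).

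Of the cell wall and histone genes singled out, XTH24, which remodels xyloglucan, was at 152 ± 87.7 CPM in control and 395 ± 110 CPM in traffic noise (DESeq2 adjusted p = 0.012). The wall protein genes EXT4, at 145 ± 51.4 and 71.4 ± 12.7 CPM, and FLA8, at 768 ± 67.2 and 485 ± 37.5 CPM, were lower (DESeq2 adjusted p = 0.034 and 0.0256). Among histones HTA11 was at 68.4 ± 12.6 and 32.2 ± 3.23 CPM and AT5G10400 at 148 ± 28.5 and 66.5 ± 11.8 CPM (DESeq2 adjusted p = 0.0183 and 0.00463). DESeq2 called 5 of 29 histone genes lower (Fisher's exact test, adjusted p = 0.0115) and 4 of 13 extensins (adjusted p = 0.0058), a test that takes genes as independent. With an estimated correlation neither family passed camera (adjusted p = 0.662 for each), and without control replicate 1 only 20 of DESeq2's 130 lower calls were kept. EdgeR called none of these genes, and of DESeq2's calls on simulated loci with at least 500 counts 17.7% were false.

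Ribosomal protein transcripts were lower in traffic noise by a median log2 fold change of -0.46. As a family they passed camera only at its preset correlation (adjusted p = 0.662 with an estimated one, 0.420 by fry), so the difference itself is uncertain. A shift of short transcripts against long ones is argued against, since the family lay -0.45 from protein-coding genes matched on length and abundance, whose median was -0.01 and ranged from -0.14 to 0.13 over 1000 draws. A single control library is argued against as well: with each control library left out in turn, the median nearest to 0 was -0.37. A low-energy response, in which plants short of sugar curb ribosome production, may be a candidate explanation. Of 14 tested marker genes of that state, listed after the DESeq2 calls were seen and without any called gene, 13 had positive fold changes (median 0.66, camera p = 0.000822), and the fits with a library left out gave a camera p of 7.9e-05 to 0.022; but the camera p was 0.284 with an estimated correlation, and 3 of the other 9 splits gave a camera p of 0.031, 0.0056 and 1.5e-05, so this stays open, as does the noise treatment itself.

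Counts of structural RNAs were lower in traffic noise for several classes. A smaller capture of all non-polyadenylated RNA would lower them alike. The mean share of plastid 23S rRNA differed by 0.0691 on the log2 scale and that of nuclear 18S rRNA by -1.16. This comparison was chosen after the shares were seen, so it cannot decide on that explanation. The 23S shares were also spread widely in control, at 9.87%, 6.78% and 5.83%, against 7.13%, 7.73% and 8.17% in traffic noise. Plastid 16S rRNA differed by -0.96, in line with the other lowered classes and unlike 23S. A difference in capture between RNA kinds, and the treatment, were not tested and stay open.

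Control replicate 3 stood apart from the other libraries by its missing loci. Its smaller total does not account for this, since the other libraries thinned to that total still had counts on at least 19983 loci, against 16128. Fewer independent molecules in the library may account for it. The share at 0 among loci with 50 to 200 counts elsewhere was 10.5 times the highest share in another library, and 0% of loci with 2000 or more counts were at 0. No biological explanation was tested, since the design names none within a group.

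The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. EdgeR called 2 loci in the real split and at most 0 in the others, so 1 split reached that count, and DESeq2 called 214 against at most 48, which 1 split reached. The real split gave 1 list past the threshold and the highest other gave 2, with 7 splits reaching 1. For families it gave 6 against at most 2, and 1 split reached 6. The ribosomal protein family passed camera's preset-correlation test in 3 of the other splits, with an adjusted p as small as 7.3e-09.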
